A study of Homo sapiens with 18 samples.

How the data were processed

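RNA was sequenced from BJ cells, a line of human foreskin fibroblasts, in 18 libraries that form 9 groups of 2. The cells were left without vector (mock) or received an adenovirus vector that expressed green fluorescent protein (GFP) alone or GFP with VP55, a vaccinia virus poly(A) polymerase subunit that adds tails to microRNAs (miRNAs) and was delivered to deplete them. Cells were collected 24 h or 9 days after the vector, or were then treated with interferon beta (IFN) for 6 h or with double-stranded RNA (dsRNA) for 8 h. Each IFN or dsRNA group therefore differs from the 24 h group of the same vector in total time as well as in the treatment.

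Per the labels' protocols, total RNA was extracted with Trizol and mRNA libraries were made with the TruSeq RNA v2 kit. By its design this kit selects poly(A) RNA and does not mark strand, which the labels do not state. Per the submitters' processing notes, the genome build was hg19. The aligner and the counting program are not given in the sources used here. The deposited file is a table of raw read counts per gene symbol, 1 column per library, in whole numbers with no normalization. Of its rows, 28 have a date in place of a gene symbol, as spreadsheet programs write some symbols, and hold between 0.152% and 0.325% of the counts of a library. These rows were left out, which left 23682 symbols. Total counts ranged from 51587 in GFP+IFN replicate 1 to 5408376 in mock replicate 1. In the shallowest library 1 count equals 17.6 CPM (counts scaled to a common library total) and in the deepest 0.168 CPM. Nothing in the labels says that the 2 libraries of a group are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

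Replicates were compared by a chi-square test of their counts over genes with at least 50 counts in the pair. The statistic per degree of freedom was 1.13 for GFP 9 day, 1.18 for VP55 9 day and 1.76 to 3.71 in others without dsRNA. It was 25.6 for GFP+dsRNA and 19 for VP55+dsRNA, so a fit of all groups may understate their spread. The 9 day pairs thus differed by slightly more than counting noise and were kept as 2 libraries, with summing tried as an alternative. Replicate numbers do not pair libraries across groups.

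Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test after trimmed mean (TMM) scaling. The filter filterByExpr kept 12320 genes. All 18 libraries entered 1 fit with a mean per group and no covariate, which leaves 9 residual degrees of freedom. There were 10 comparisons of 2 groups and 3 interactions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and every adjusted p of a gene below is from this test unless another is named. Levels are given in CPM with TMM scaling, as mean ± SD of 2 libraries, and fold changes on the log2 scale ± SE. A fold against a group with 0 counts is a lower bound computed with 3 counts over that group. Where a group holds 1 to 3 counts, the ratio of the counts summed over the 2 libraries, scaled by their summed library sizes, is given with an exact 95% interval. It can differ from the ratio of the mean levels. Such intervals and bounds cover counting error only.

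Gene lists were fixed before the data were examined. They hold interferon-stimulated genes, type I and III interferons, cytokines and chemokines, NF-kB targets, cell cycle genes, p53 targets, extracellular matrix genes, textbook miRNA targets, genes of the miRNA pathway and RNA tailing, miRNA host transcripts, genes of the unfolded protein and integrated stress response, cholesterol synthesis genes, replication-dependent histones, small non-coding RNA genes, miRNA precursor genes, mitochondrial genome genes, fibroblast identity genes, and markers of keratinocytes, leukocytes, endothelial cells and melanocytes. The mitochondrial list had 0 genes in the table and the melanocyte list 0 genes tested. The 16 lists with at least 5 tested genes were tested as sets with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists of a comparison. The test was repeated with an estimated correlation: of 98 list calls in 208 tests, 19 held. Each list also has the number of members called when adjusted over the list alone.

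Sets of genes with an 8mer seed site in the 3′ UTR were tested for 27 miRNA families of fibroblasts and 7 control families. The median log2 fold change of a set was compared with that of 10000 random sets, drawn from genes with the site or with no 6mer of the family and matched on 3′ UTR length and mean expression in 10 bins each, over 11543 genes (Python 3.11.15, numpy 2.4.6). The smallest p these sets can give is 1e-04. Sets also matched on GC content used 5 bins each of length and expression and 10 of GC, and sets with 5 bins and no GC matching were drawn beside them. Gene names, 3′ UTRs and overlap between genes came from GENCODE v29 (GRCh38). It matched 22792 of the symbols, and 96.2% had exon models. Since that build is not the one of the counts, no coordinates are given. A gene was taken as overlapping when its exons, or its RefSeq gene range, overlap those of another gene of the table. This holds for 8507 genes of the table and for 36.5% of the genes tested. With no strand, reads of overlapping and antisense genes cannot be told apart. Such genes, histone genes, which are near-identical copies, and other multigene families are therefore uncertain.

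The genes named were picked by a rule fixed before the data were examined. Among genes called, with a mean of at least 1 CPM and both replicates of a group above both of the other, these are the 6 largest increases and the 6 largest decreases, and up to 4 called members of each list. In a list with no called member, up to 2 of its most abundant genes could be named. Unnamed loci were skipped. Of the genes this rule picked, the text mostly names those whose call held with every library left out, a choice made after their values were seen.

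The steps were tested on simulated counts with 200 changed genes among the 12320. At VP55 24 h against GFP 24 h, 19% of the 2-fold and 62% of the 4-fold changes were called. At GFP+IFN against GFP 24 h these were 5% and 64%, and at VP55+IFN against GFP+IFN 13% and 55%. At GFP+dsRNA against GFP 24 h they were 23% and 77%, and at VP55+dsRNA against GFP+dsRNA 14% and 72%. Of the genes called, some had not been changed: 3 of 85 for VP55 24 h, 3 of 74 for GFP+IFN, 9 of 126 for GFP 24 h against mock, 7 of 75 for VP55+IFN, 11 of 113 for VP55 9 day, 11 of 112 for GFP+dsRNA and 14 of 103 for VP55+dsRNA, a share above 5% in the last 5. A list of 40 genes moved 1.5-fold was called in each of these comparisons, and 0 of 20 unchanged lists were. A shift of 0.2 for let-7 sites was estimated as 0.154, with 0 of 33 other families called. Neither simulation speaks for correlated genes or seed shifts under 0.2, and the wider spread of dsRNA pairs may make their shares too favourable.

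Alternatives were DESeq2 1.42.0, relative log expression or library size scaling in place of TMM, no filter or a stricter filter (1 CPM in 4 libraries), the replicate number as a block, only the compared groups in the fit, calls of at least 2-fold, another site definition, and each library left out in turn. Where that leaves a group with 1 library, the lone library is assumed to vary like the other groups. Added after the data were seen were tests without overlapping genes, mock in place of GFP 24 h, summed 9 day pairs, a crossed block for the dsRNA groups, random sets also matched on 3′ UTR GC content, and random sets in 5 bins of length and expression.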

Results

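Read counts per gene were available for 18 libraries, 2 in each of 9 groups. Total counts were 5408376 and 1399355 in mock cells, 857642 and 2673853 at GFP 24 h, and 347145 and 1118113 at VP55 24 h. They were 4162951 and 1011410 at GFP 9 day and 2608350 and 569141 at VP55 9 day. After interferon beta they were 51587 and 1403439 with GFP and 407369 and 1602078 with VP55. After dsRNA they were 2700003 and 1917228 with GFP and 1346214 and 312684 with VP55. Every mean below is over n = 2 libraries with its SD. The table has no entry for VP55, GFP or mature miRNAs, so neither the vectors named in the labels nor the loss of miRNAs could be checked. Markers of other cell types were few: 4 tested genes for keratinocytes or epithelium, 2 for leukocytes and 2 for endothelium.

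Genes that share exons or gene ranges with a neighbour split the libraries in a way that followed neither vector nor treatment alone. In the 6 libraries of GFP 24 h, GFP+dsRNA and VP55+dsRNA, the cytokine gene MIF averaged 0 CPM against 126 CPM in the other 12 libraries. SNX22 averaged 4.44 CPM against 418 CPM, and the pseudogene WTAPP1 47.2 CPM against 1460 CPM. Genes with over 30% of their exons shared, 361 in all, had a median log2 fold change of VP55 over GFP at 24 h that was 0.313 above that of 7699 genes with no overlap. Calls in comparisons that set these 6 libraries against others are therefore also given without overlapping genes. The seed-site test was not repeated without them.

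**Figure D1:**
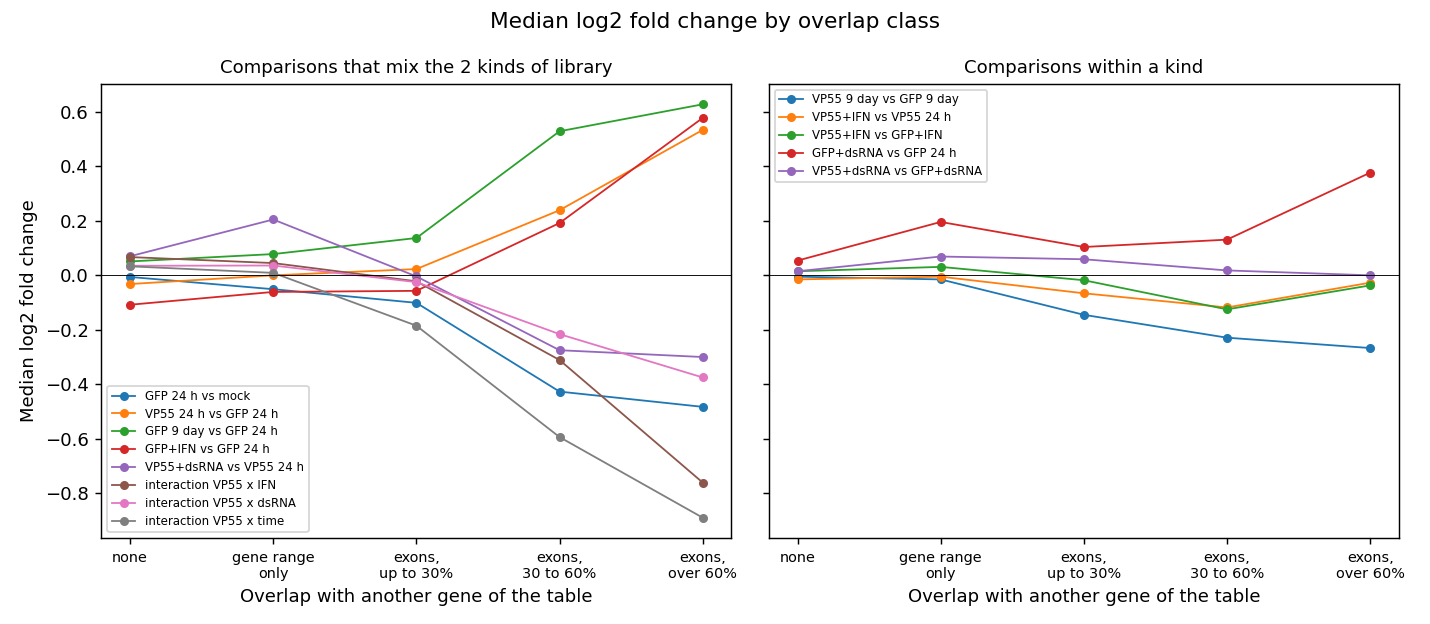
Median log2 fold change of genes grouped by how much of their exons another gene shares, for each comparison, with comparisons that mix the 6 libraries with others set apart from those that do not. The difference between genes over 30% shared and genes with no overlap was 0.313 to 0.682 in size in the 8 mixed results and 0.001 to 0.237 in the other 5.

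The control vector was compared with mock cells at 24 h. Interferon-stimulated genes, which respond to antiviral signalling, rose: 30 of 54 tested members were called higher, or 33 adjusted over the list alone. BST2, which tethers virus particles to the cell, went from 2.73 ± 0.763 to 76.9 ± 9.78 CPM, a log2 fold change of 4.91 ± 0.64. OAS1, an enzyme activated by dsRNA, went from 1.48 ± 0.672 to 20.5 ± 1.91 CPM (3.95 ± 0.65). Cell cycle genes fell, with 20 of 35 called lower and 1 higher (23 lower and 1 higher adjusted over the list alone). CDC6, needed to start DNA replication, went from 57.6 ± 10.4 to 9.07 ± 1.46 CPM (−2.62 ± 0.39).

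Of 37 cytokine and chemokine genes, 15 were called lower with the control vector and 1 higher (16 and 1 adjusted over the list alone). The neutrophil chemokine CXCL6 fell from 236 ± 184 to 1.84 ± 0.974 CPM (−6.74 ± 0.57), against a wide spread in mock cells. IL33 fell from 46.1 ± 27.3 to 0.574 ± 0.812 CPM, a ratio of summed counts of 0.00477 (95% interval 0.000121 to 0.0267). Of 31 extracellular matrix genes, 15 were called higher and 4 lower (17 and 5 adjusted over the list alone). The collagen gene COL1A1 rose from 10200 ± 2690 to 28200 ± 1780 CPM (1.47 ± 0.29), while the proteoglycan gene DCN fell from 3270 ± 32.9 to 511 ± 39.1 CPM (−2.67 ± 0.39). PDGFRA, a growth factor receptor of fibroblasts, fell from 683 ± 41.4 to 112 ± 4.41 CPM (−2.61 ± 0.3). Among 18 cholesterol synthesis genes 9 were called higher (11 adjusted over the list alone), such as DHCR7 at 78.6 ± 0.922 against 28.2 ± 5.38 CPM (1.51 ± 0.27). Among 24 p53 targets 9 were called higher (13 higher and 1 lower adjusted over the list alone), such as the cell cycle inhibitor CDKN1A at 1020 ± 90.3 against 410 ± 27.6 CPM (1.32 ± 0.27). The heart actin gene ACTC1 had 0 counts in mock cells and was at least 19.3-fold higher with GFP. Of 55 histone genes 7 were called higher (7 adjusted over the list alone), and of 12 miRNA precursor genes 3 were called lower (3 adjusted over the list alone).

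In the camera set tests of this comparison the adjusted p was 7.36e-19 for interferon-stimulated genes, 2.78e-14 for cell cycle genes and 0.000693 for cytokines. It was 0.000216 for matrix genes, 2.24e-05 for cholesterol synthesis, 0.000147 for p53 targets, 0.0113 for histones and 0.0106 for miRNA precursors. With an estimated correlation the cell cycle call held (adjusted p = 0.0402). The others were lost, at adjusted p = 0.252 for interferon-stimulated, matrix, cholesterol and miRNA precursor genes, 0.407 for cytokines, 0.17 for p53 targets and 0.342 for histones. The edgeR quasi-likelihood test called 876 genes higher and 1271 lower, 2147 in all, and 513 higher and 598 lower without overlapping genes. The total of 2147 fell to 725 without mock replicate 1, 1279 without mock replicate 2, 1071 without GFP 24 h replicate 1 and 898 without GFP 24 h replicate 2.

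VP55 was compared with GFP at 24 h. NF-kB targets were higher with VP55 as a set, and 7 of 37 cytokines were called higher. IL8, a neutrophil chemokine, was at 166 ± 19.4 CPM with VP55 and 4.28 ± 0.442 CPM with GFP, a log2 fold change of 5.31 ± 0.71 (adjusted p = 8.16e-05). Mock cells had 122 ± 127 CPM of it. GADD45A, a stress gene and p53 target, was at 274 ± 8.91 against 69.6 ± 2.61 CPM (1.97 ± 0.28), and at 40.4 ± 0.203 CPM in mock cells. Both calls held with every library left out.

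Of 22 NF-kB targets, 8 were called higher with VP55 at 24 h (18 adjusted over the list alone). NFKBIA, the inhibitor of NF-kB, was at 234 ± 7.95 against 49 ± 9.25 CPM (2.23 ± 0.41) and at 42.5 ± 17.5 CPM in mock cells. Its adjusted p was 0.0563 without GFP 24 h replicate 1 and 0.0708 without replicate 2. TNFAIP3, which dampens NF-kB signalling and overlaps another gene, was at 206 ± 6.02 against 23.5 ± 2.56 CPM (3.16 ± 0.34). Of 37 cytokines, 7 were called higher (11 adjusted over the list alone). CXCL1 was at 204 ± 32.1 against 12.1 ± 0.768 CPM (4.07 ± 0.64), with an adjusted p of 0.0694 without GFP 24 h replicate 2. Mock cells had 260 ± 276 CPM of CXCL1, so it was the GFP level that stood below the other 2 groups. The transcription factor EGR1, chosen after its values were seen, was at 185 ± 73.6 with VP55, 20.1 ± 7.3 with GFP and 250 ± 63.2 CPM in mock cells. Of 24 p53 targets, 5 were called higher (8 adjusted over the list alone).

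**Figure D2:**
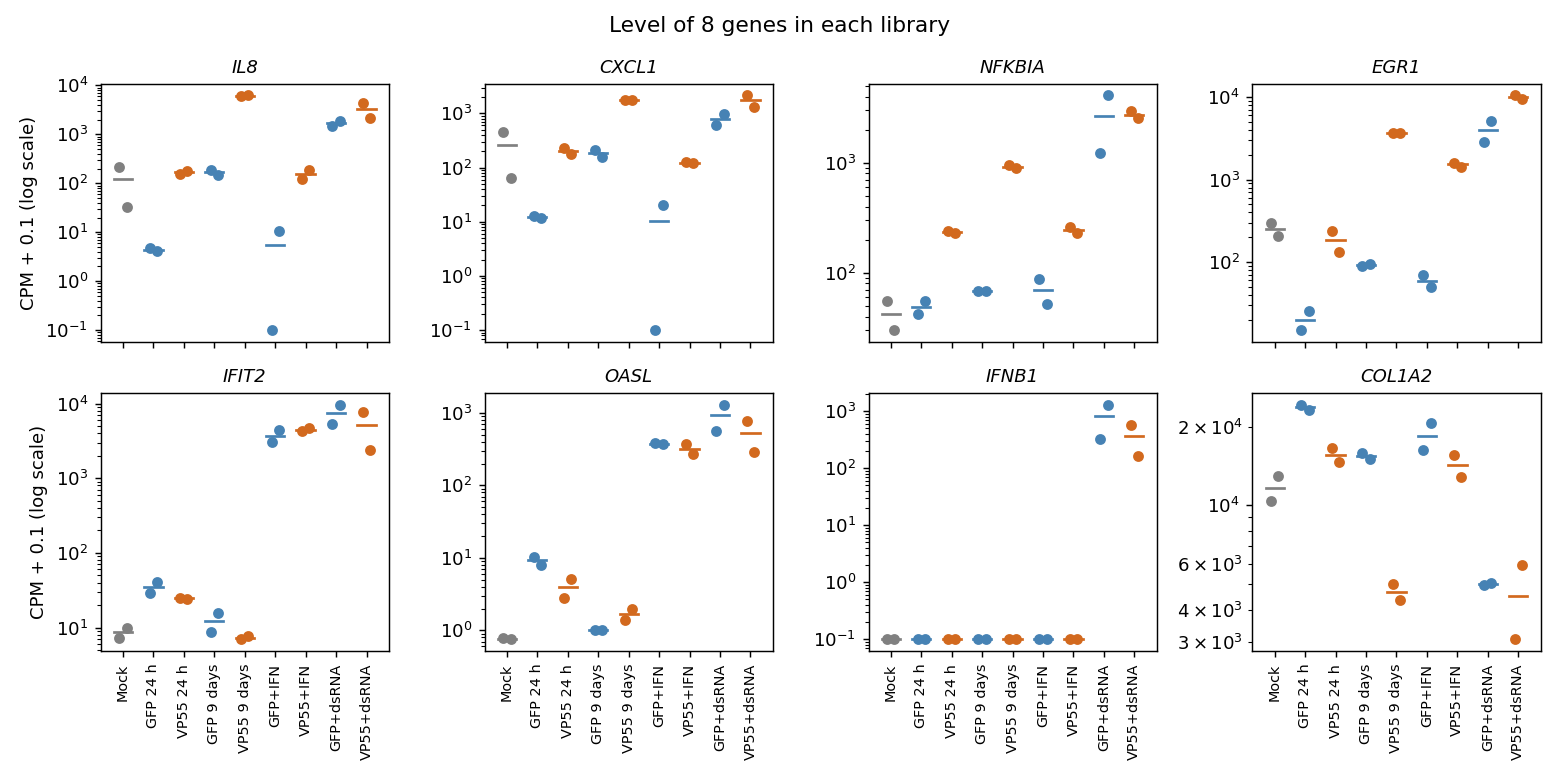
Level of IL8, CXCL1, NFKBIA, EGR1, IFIT2, OASL, IFNB1 and COL1A2 in each library, in CPM plus 0.1 on a log scale, by group, with points for libraries and lines for group means. IL8 averaged 4.28 CPM at GFP 24 h, 122 CPM in mock cells and 6150 CPM at VP55 9 day, and IFNB1 had 0 CPM in all groups without dsRNA.

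Replication-dependent histones, whose mRNAs end without a poly(A) tail, rose with VP55 at 24 h, with 13 of 55 called higher (28 adjusted over the list alone). HIST1H1D was at 22.6 ± 14.3 CPM and HIST1H3J at 19 ± 7.88 CPM with VP55, both with 0 counts in GFP cells, so at least 27.5-fold and 23.0-fold higher. Both calls rested on GFP 24 h replicate 2, without which the adjusted p was 0.246 and 0.194. Of 18 small non-coding RNA genes 2 were called higher (3 adjusted over the list alone), among them the minor spliceosome RNA RNU12 at 15.4 ± 5.2 CPM against 0 counts, at least 18.7-fold higher. The RNU12 call was lost without GFP 24 h replicate 2 (adjusted p = 0.38), VP55 24 h replicate 1 (0.0588) or VP55 24 h replicate 2 (0.114). Of 12 miRNA precursor genes 2 were called higher (3 adjusted over the list alone). One of these, MIR1282, overlaps another gene and had 0 counts at GFP 24 h.

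Interferon-stimulated genes did not pass: the edgeR quasi-likelihood test called 0 of 54, with 2 higher and 1 lower at an unadjusted p under 0.05 and 1 higher by DESeq2. The set missed as well (adjusted p = 0.39) but was lower without VP55 24 h replicate 2 (0.00193). The edgeR test also called 0 of 31 matrix genes (1 higher and 7 lower at an unadjusted p under 0.05, 1 higher by DESeq2) and 0 of 10 fibroblast identity genes (2 lower and, by DESeq2, 0). As sets both were lower by camera, at adjusted p = 2.7e-05 and 0.0105, but adjusted p = 0.183 with an estimated correlation for either. The textbook miRNA targets, genes known to be repressed by miRNAs, had 1 of 42 called higher (4 adjusted over the list alone) and missed as a set (adjusted p = 0.0612, and 0.36 with an estimated correlation). The set passed as higher without overlapping genes (0.00115), with no low-count filter (0.0326), with library sizes (0.0433) and without GFP 24 h replicate 2 (0.0312). The miRNA pathway list had 1 of 21 called, TNRC6B, a protein of the silencing complex, at 73.8 ± 11.8 against 26.5 ± 1.78 CPM (1.49 ± 0.26). Its adjusted p was 0.06 and 0.164 without GFP 24 h or VP55 24 h replicate 2 and 0.0739 with mock in place of GFP 24 h. The list missed as a set (0.323) but was higher without overlapping genes (0.0133).

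By camera the adjusted p at 24 h was 6.97e-22 for NF-kB targets (adjusted p = 0.00851 with an estimated correlation), 3.38e-21 for histones (0.00851), 5.69e-06 for p53 targets (0.0411) and 9.05e-06 for miRNA precursors (0.0484). It was 9.1e-10 for cytokines and 0.0131 for small non-coding RNA genes, calls lost at adjusted p = 0.132 and 0.403 with an estimated correlation. With mock in place of GFP 24 h the cytokine call was lost at adjusted p = 0.767 and that of miRNA precursors at 0.964, and with no low-count filter the latter was lost at 0.609 and small non-coding RNA genes turned to the lower side (0.52). In all 263 genes were called, 259 higher and 4 lower, of which 190 overlap another gene, 72.2% of the calls against 36.5% of the genes tested. Without overlapping genes 42 were called, all higher, among them IL8, CXCL1, NFKBIA, GADD45A and HIST1H1D. The 263 fell to 177 and 63 without GFP 24 h replicate 1 or 2 and to 171 and 93 without VP55 24 h replicate 1 or 2, and VP55 24 h against mock gave 824 higher and 827 lower.

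**Figure D3:**
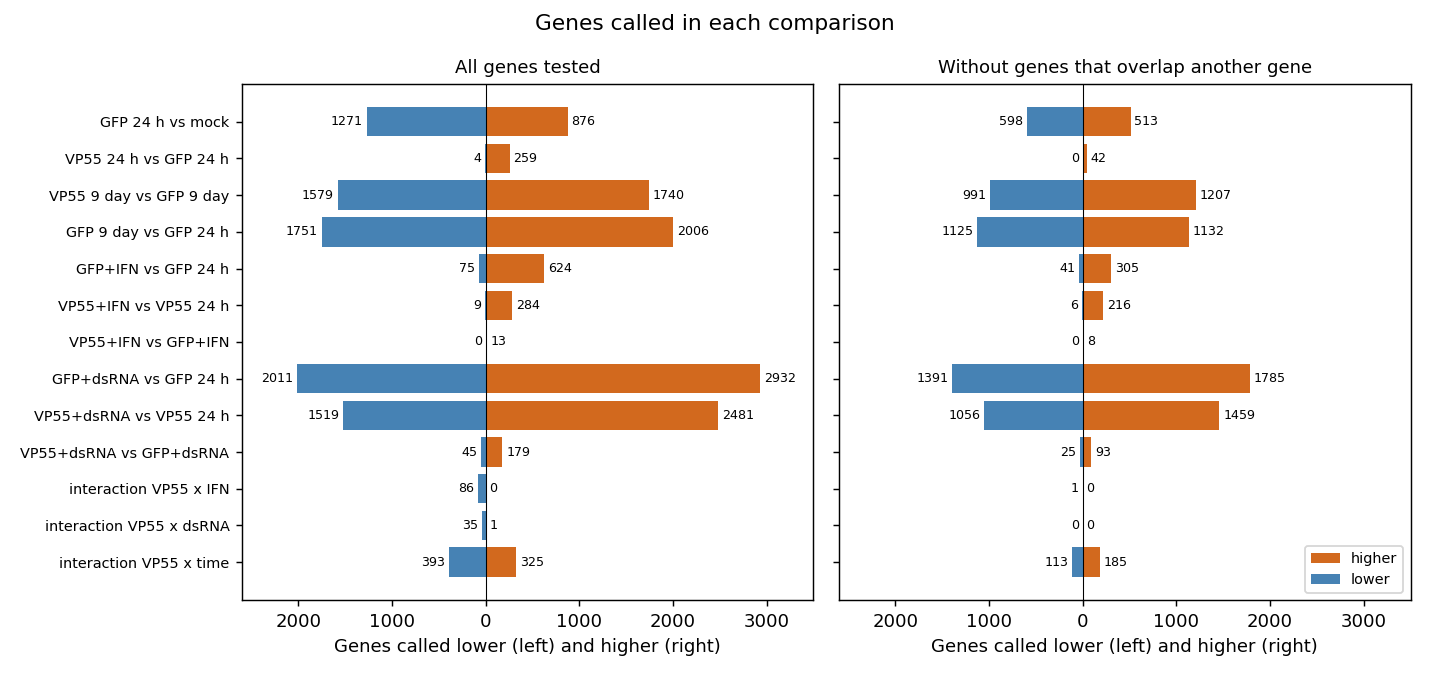
Number of genes called higher (bars to the right) and lower (bars to the left) in each comparison by the edgeR quasi-likelihood test, over all 12320 genes and without overlapping genes. VP55 against GFP at 24 h had 259 higher and 4 lower, or 42 higher without overlapping genes.

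At 9 days VP55 was again compared with GFP. The colony-stimulating factor CSF3 was at 675 ± 70.6 against 3.85 ± 2.86 CPM, a log2 fold change of 7.1 ± 0.79. The interleukin 6 family cytokine LIF was at 973 ± 36.3 against 11.2 ± 1.66 CPM (6.38 ± 0.59), and IL1B at 1470 ± 55 against 19.2 ± 3.84 CPM (6.2 ± 0.71). Mock cells had 6.37 ± 7.17, 13.2 ± 14.1 and 38.7 ± 33.5 CPM of these. Of 37 cytokines 17 were called higher and 2 lower (19 and 2 adjusted over the list alone). NF-kB targets rose, with 19 of 22 called (19 adjusted over the list alone), such as the prostaglandin synthase gene PTGS2 at 2550 ± 22.4 against 147 ± 10.1 CPM (4.11 ± 0.41).

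Cholesterol genes rose with VP55 at 9 days, 10 of 18 (10 adjusted over the list alone). Matrix genes went both ways, with 6 of 31 called higher and 15 lower (6 and 17 adjusted over the list alone): SPARC fell from 9480 ± 116 to 2220 ± 55.5 CPM (−2.09 ± 0.24) and COL5A3 rose from 79 ± 10.8 to 372 ± 13.2 CPM (2.22 ± 0.27). Of 10 fibroblast identity genes 1 was called higher and 4 lower (4 and 4 adjusted over the list alone), among them COL1A2 at 4680 ± 466 against 15400 ± 614 CPM (−1.72 ± 0.27). Of 24 p53 targets 10 were called higher and 1 lower (11 and 1 adjusted over the list alone), such as DDB2 at 94.5 ± 16.8 against 23.5 ± 0.374 CPM (2.04 ± 0.28). Interferon-stimulated genes had 2 called higher and 12 lower of 54 (2 and 12 adjusted over the list alone). In the stress response list 8 of 19 were called higher and 2 lower (8 and 2 adjusted over the list alone). PPP1R15A, which reverses a translation block, was at 1080 ± 24.5 against 167 ± 11.6 CPM (2.7 ± 0.35), and the asparagine synthetase gene ASNS at 11.6 ± 0.53 against 64.1 ± 11.8 CPM (−2.46 ± 0.35).

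The miRNA pathway list had 5 of 21 called higher and 2 lower at 9 days (5 and 2 adjusted over the list alone), and missed as a set (adjusted p = 0.312). The Argonaute gene AGO2 was at 80.1 ± 12.4 against 21.4 ± 4.69 CPM (2 ± 0.3), and the uridylyltransferase gene ZCCHC6 at 231 ± 7.87 against 69.4 ± 3.71 CPM (1.73 ± 0.25). Of 18 small non-coding RNA genes 5 were called higher (5 adjusted over the list alone), such as the minor spliceosome RNA RNU11 at 47.5 ± 7.13 against 0.113 ± 0.16 CPM, a ratio of summed counts of 245 (95% interval 43.2 to 9750). Histones had 16 of 55 called higher and 3 lower (16 and 5 adjusted over the list alone), while their summed level was 724 ± 7.78 CPM with VP55 and 807 ± 15.6 CPM with GFP. Cell cycle genes had 11 of 35 called higher and 1 lower (12 and 1 adjusted over the list alone), and textbook miRNA targets 10 of 42 higher and 5 lower (11 and 5 adjusted over the list alone). As sets the textbook targets (adjusted p = 0.389) and fibroblast identity genes (0.508) missed.

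By camera NF-kB targets had an adjusted p of 6.39e-18 (adjusted p = 0.0365 with an estimated correlation). The other list calls at 9 days were lost with an estimated correlation: cytokines (7.45e-08, then adjusted p = 0.311), cholesterol (4.43e-05, 0.345), p53 targets (0.000596, 0.246), small non-coding RNA genes (0.00529, 0.357, on the lower side at 0.399 with no low-count filter), histones (0.00866, 0.352), interferon-stimulated genes (0.00883, 0.649), matrix (0.00883, 0.385), cell cycle (0.0109, 0.357) and stress response (0.0406, 0.345). The adjusted p for the stress response list was 0.0536 and 0.0671 without GFP 9 day replicate 1 or 2, for cell cycle 0.163 without VP55 9 day replicate 1, and for matrix 0.0726 without VP55 9 day replicate 2. In all 1740 genes were called higher and 1579 lower by edgeR, 3319 in all, but 1252 higher and 2503 lower with library sizes in place of TMM scaling, which moved the median of all genes to −0.283. The 3319 fell to 1471 and 1953 without GFP 9 day replicate 1 or 2, to 1222 and 2195 without VP55 9 day replicate 1 or 2, and to 1096 with each pair summed to 1 library.

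GFP at 9 days against GFP at 24 h shows what time with the control vector changed. Cell cycle genes fell, with 32 of 35 called lower and 1 higher (32 and 1 adjusted over the list alone). BIRC5, an inhibitor of cell death made in mitosis, went from 47.4 ± 12.5 to 0.796 ± 0.168 CPM (−5.84 ± 0.51), and the thymidine kinase gene TK1 from 63.3 ± 14.5 to 1.25 ± 0.814 CPM (−5.95 ± 0.44). Interferon-stimulated genes fell, with 30 of 54 called lower and 3 higher (32 and 3 adjusted over the list alone). MX1, an antiviral GTPase, went from 130 ± 38.5 to 12.4 ± 0.594 CPM (−3.38 ± 0.48).

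Cytokines had 14 of 37 called higher at 9 days and 2 lower (15 and 2 adjusted over the list alone), and NF-kB targets 9 of 22 higher (10 adjusted over the list alone). ICAM1, an adhesion molecule for leukocytes, was at 555 ± 22.1 against 93.9 ± 13.4 CPM (2.58 ± 0.3), and IL8 at 167 ± 31.3 against 4.28 ± 0.442 CPM (5.31 ± 0.7). Cholesterol genes had 9 of 18 called lower (10 adjusted over the list alone), such as DHCR7 at 17.8 ± 7.07 against 78.6 ± 0.922 CPM (−2.02 ± 0.29). DCN returned to 3150 ± 59.4 CPM and PDGFRA to 588 ± 21.3 CPM, near their mock levels. The tryptophan dioxygenase gene TDO2 was at 357 ± 27.5 against 0.18 ± 0.255 CPM, a ratio of summed counts of 1260 (95% interval 226 to 49700). Histones had 14 of 55 called higher (13 adjusted over the list alone), such as HIST1H4E at 40.6 ± 2.14 against 1.87 ± 0.604 CPM (4.54 ± 0.39), and miRNA precursors 4 of 12 (4 adjusted over the list alone).

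The camera adjusted p was 3.16e-31 for cell cycle genes (0.0083 with an estimated correlation). It was 3.62e-08 for interferon-stimulated genes and 0.00112 for cytokines, both lost at adjusted p = 0.386 with an estimated correlation. It was 0.00144 for NF-kB targets, 0.000432 for cholesterol, 0.00158 for histones and for miRNA precursors, each likewise lost at adjusted p = 0.356. By edgeR 2006 genes were called higher and 1751 lower, 3757 in all, and 1132 and 1125 without overlapping genes. The 3757 fell to 2276 and 2306 without GFP 24 h replicate 1 or 2, to 1809 and 2467 without GFP 9 day replicate 1 or 2, and to 2122 with the 9 day pair summed.

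Interferon beta for 6 h after the control vector was compared with GFP at 24 h. Interferon-stimulated genes rose, with 46 of 54 called higher (50 adjusted over the list alone). OASL, an antiviral protein of the OAS family, went from 9.14 ± 1.7 to 377 ± 13.9 CPM, a log2 fold change of 5.41 ± 0.5, and mock cells had 0.663 ± 0.014 CPM. IFIT2, which binds viral RNA and overlaps another gene, went from 34.7 ± 8.53 to 3730 ± 948 CPM (6.71 ± 0.5). Of 37 cytokines 11 were called higher (12 adjusted over the list alone), such as the death ligand TNFSF10 (6.06 ± 0.59, from 1.26 ± 1.79 CPM), with an adjusted p of 0.247 without GFP+IFN replicate 2. Of 18 cholesterol genes 1 was called lower (2 adjusted over the list alone), and of 12 miRNA precursors 3 were called higher (4 adjusted over the list alone), with MIR1282, an overlapping gene, among them.

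By camera the adjusted p was 1.59e-97 for interferon-stimulated genes (0.0167 with an estimated correlation) and 6.76e-09 for cytokines, lost at 0.319. For miRNA precursors it was 6.08e-05, lost at 0.0907. The cholesterol call, at 0.0346, was lost at adjusted p = 0.86 with an estimated correlation, at 0.0709 without GFP 24 h replicate 2 and at 0.0697 without GFP+IFN replicate 1. In all 624 genes were called higher and 75 lower, 699 in all, and 305 and 41 without overlapping genes. The total was 729 without the shallow GFP+IFN replicate 1, in which the untailed RNAs RMRP and RPPH1 summed to 2280 CPM against 2.28 CPM in replicate 2, but 66 without GFP+IFN replicate 2 and 324 without GFP 24 h replicate 2.

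The same treatment after VP55 was compared with VP55 at 24 h. Of 54 interferon-stimulated genes 44 were called higher (51 adjusted over the list alone): OASL went from 3.88 ± 1.63 to 321 ± 69.2 CPM (6.14 ± 0.59), and IFIT2 from 24.4 ± 0.173 to 4500 ± 268 CPM (7.52 ± 0.55). The tryptophan-degrading enzyme gene IDO1 was at 69.3 ± 6.58 CPM against 0 counts, at least 36.1-fold higher, and TNFSF10 at 111 ± 14.6 CPM against 0 counts, at least 57.9-fold higher. Of 37 cytokines 7 were called higher (13 adjusted over the list alone). The stress factor gene ATF3 was at 115 ± 13.2 against 8.9 ± 8.74 CPM (3.33 ± 0.59). By camera the adjusted p was 2.43e-140 for interferon-stimulated genes (0.00298 with an estimated correlation) and 6.11e-09 for cytokines, lost at 0.391. The edgeR test called 284 genes higher and 9 lower, 293 in all. That total fell to 164 and 97 without VP55 24 h replicate 1 or 2 and to 144 without VP55+IFN replicate 2.

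Under interferon beta, VP55 and GFP were compared directly, which called 13 genes, all higher with VP55. EGR1 was at 1520 ± 122 against 59.8 ± 14.8 CPM, a log2 fold change of 4.87 ± 0.42 (adjusted p = 2.12e-06), and at 250 ± 63.2 CPM in mock cells. Its call held with every library left out, and those of the other 12 genes did not. TNRC6B was at 105 ± 8.16 against 22.1 ± 6.38 CPM (2.01 ± 0.31), with an adjusted p of 0.709 and 0.103 without GFP+IFN or VP55+IFN replicate 2. The NF-kB inhibitor gene NFKBIZ, which overlaps another gene, was at 446 ± 34.8 against 81.5 ± 15.8 CPM (2.33 ± 0.39), with an adjusted p of 0.0993 and 0.645 without GFP+IFN replicate 1 or 2 and 0.0536 and 0.202 without VP55+IFN replicate 1 or 2. Of 22 NF-kB targets 3 were called higher (12 adjusted over the list alone).

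No interferon-stimulated gene was called between VP55 and GFP under interferon: edgeR called 0 of 54, with 1 higher at an unadjusted p under 0.05 and 0 by DESeq2. For OASL the log2 fold change was −0.23 and for IFIT2 0.26, neither called. As a set they were lower by camera (adjusted p = 0.0396), a call lost at adjusted p = 0.699 with an estimated correlation, and without GFP+IFN replicate 2 (0.27), VP55+IFN replicate 1 (0.134) or VP55+IFN replicate 2 (0.111). Histones had 0 of 55 called (25 higher at an unadjusted p under 0.05, 0 by DESeq2, 16 adjusted over the list alone), cytokines 0 of 37 (8 higher and 1 lower, 2 by DESeq2, 7 adjusted over the list alone) and p53 targets 0 of 24 (9 higher, 4 by DESeq2, 6 adjusted over the list alone).

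As sets, NF-kB targets were higher under interferon with VP55 by camera at adjusted p = 2.87e-20 (adjusted p = 0.0321 with an estimated correlation) and p53 targets at 3.9e-08 (0.0321). Histones (4.55e-11), cytokines (6.75e-08) and textbook miRNA targets (0.00794) were lost at adjusted p = 0.164 with an estimated correlation, and the histones also at 0.252 without GFP+IFN replicate 2. Cholesterol genes (9.47e-05) were lost at adjusted p = 0.21 with an estimated correlation. The miRNA pathway (0.0205), stress response (0.0246) and fibroblast identity (0.0397, lower) calls were lost at 0.275, 0.164 and 0.285. The pathway call also ended without GFP+IFN replicate 2 (0.59) or VP55+IFN replicate 2 (0.516), the stress response call without GFP+IFN replicate 1 (0.0706) or VP55+IFN replicate 1 (0.134), and the textbook call without VP55+IFN replicate 2 (0.106). The fibroblast identity call ended without GFP+IFN replicate 2 (0.736), VP55+IFN replicate 1 (0.134) or VP55+IFN replicate 2 (0.111). The 13 calls became 8 and 5 without GFP+IFN replicate 1 or 2 and 5 and 1 without VP55+IFN replicate 1 or 2, while 169 were called with only these 2 groups in the fit and 43 by DESeq2.

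The response to dsRNA for 8 h after the control vector was compared with GFP at 24 h. All 5 tested type I and III interferon genes were called higher (5 adjusted over the list alone). IFNB1, interferon beta itself, was at 814 ± 693 CPM against 0 counts, at least 988-fold higher, and IFNL1 at 221 ± 246 CPM against 0 counts, at least 268-fold higher. By DESeq2 neither passed (adjusted p = 0.133 and 0.214). Of 54 interferon-stimulated genes 51 were called higher (51 adjusted over the list alone), such as OASL at 934 ± 527 against 9.14 ± 1.7 CPM (6.73 ± 0.49) and HERC5 at 261 ± 98.6 against 5.07 ± 2.58 CPM (5.91 ± 0.5).

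NF-kB targets rose with dsRNA, 20 of 22 (20 adjusted over the list alone), such as CD83 at 212 ± 63.1 against 0.361 ± 0.51 CPM, a ratio of summed counts of 403 (95% interval 111 to 3330). Of 37 cytokines 33 were called higher and 1 lower (34 and 1 adjusted over the list alone): CCL20, a chemokine for dendritic cells, was at 60 ± 3.93 CPM against 0 counts, at least 72.8-fold higher. Matrix genes fell, 22 of 31 with 1 higher (22 and 1 adjusted over the list alone), and fibroblast identity genes fell, 6 of 10 (6 adjusted over the list alone). COL1A2 went from 23800 ± 738 to 5000 ± 60.6 CPM (−2.25 ± 0.28). Cell cycle genes fell, 22 of 35 (24 adjusted over the list alone), such as TOP2A at 24.4 ± 8.66 against 109 ± 14.1 CPM (−2.14 ± 0.35). Cholesterol genes fell, 10 of 18 (10 adjusted over the list alone), such as DHCR7 at 17.6 ± 6.36 against 78.6 ± 0.922 CPM (−2.12 ± 0.29). Histones rose, 38 of 55 (41 adjusted over the list alone), and small non-coding RNA genes rose, 14 of 18 (16 adjusted over the list alone). RNU11 was at 47.9 ± 38.7 CPM against 0 counts, at least 58.2-fold higher.

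Among 24 p53 targets 9 were called higher and 2 lower with dsRNA (9 and 2 adjusted over the list alone), such as GADD45A at 1070 ± 346 against 69.6 ± 2.61 CPM (3.94 ± 0.29). Textbook miRNA targets had 18 of 42 called higher and 6 lower (20 and 6 adjusted over the list alone), such as MYC at 457 ± 131 against 15.2 ± 1.99 CPM (4.86 ± 0.32). The stress response list had 6 of 19 higher and 6 lower (6 and 6 adjusted over the list alone), with ATF3 at 1290 ± 802 against 7.51 ± 3.99 CPM (7.63 ± 0.58), and missed as a set (adjusted p = 0.437), its median at −0.21 and its mean at 0.67. The miRNA host transcripts had 8 of 10 called higher (9 adjusted over the list alone) and the miRNA precursors 7 of 12 (7 adjusted over the list alone).

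Camera list calls that held for dsRNA after GFP were NF-kB targets (3.49e-25, adjusted p = 0.0141 with an estimated correlation), cytokines (1.36e-21, 0.0441) and cell cycle (4.93e-10, 0.0352). Those lost were interferon-stimulated genes (3.53e-33, then 0.0509), histones (2.14e-11, 0.0509), matrix (3.38e-10, 0.0509), interferons (4.09e-06, 0.0568), fibroblast identity (0.000193, 0.0568), cholesterol (2.21e-06, 0.092), small non-coding RNA genes (0.000132, 0.151), miRNA host transcripts (0.00328, 0.242), textbook targets (0.00885, 0.141), p53 targets (0.014, 0.151) and miRNA precursors (0.0159, 0.187). The precursor call also ended without GFP+dsRNA replicate 1 (0.0944). By edgeR 2932 genes were called higher and 2011 lower, 4943 in all, which fell to 2766 without GFP 24 h replicate 2.

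After VP55, dsRNA was compared with VP55 at 24 h. The early response genes FOSB and EGR4 were at 1710 ± 1020 and 245 ± 120 CPM against 0 counts, at least 889-fold and 128-fold higher. IFNB1 was at 367 ± 288 CPM against 0 counts, at least 191-fold higher, with an adjusted p of 0.255 by DESeq2. All 5 interferon genes were called higher (5 adjusted over the list alone), 43 of 54 interferon-stimulated genes were higher and 1 lower (46 and 2), 25 of 37 cytokines higher and 1 lower (27 and 1) and 20 of 22 NF-kB targets higher (20), each in brackets as adjusted over the list alone. OASL was at 535 ± 344 against 3.88 ± 1.63 CPM (6.93 ± 0.59) and CD83 at 502 ± 438 against 2.62 ± 0.151 CPM (7.63 ± 0.72).

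Matrix genes fell with dsRNA after VP55, 21 of 31 with 1 higher (21 and 2 adjusted over the list alone), as did 5 of 10 fibroblast identity genes with 1 higher (6 and 1 adjusted over the list alone). COL1A1 went from 20100 ± 3350 to 6350 ± 2310 CPM (−1.67 ± 0.29). Of 18 cholesterol genes 7 fell (7 adjusted over the list alone), such as DHCR7 at 14.9 ± 1.64 against 89.6 ± 7.17 CPM (−2.65 ± 0.38). Histones rose, 33 of 55 (40 adjusted over the list alone), with HIST1H4K at 34.9 ± 13 against 1.36 ± 1.93 CPM, a ratio of summed counts of 62.1 (95% interval 10.7 to 2500). Small non-coding RNA genes rose, 11 of 18 (12 adjusted over the list alone), p53 targets 13 of 24 (13) and miRNA host transcripts 7 of 10 (9). BTG2, a p53 target that slows division, was at 939 ± 189 against 82.6 ± 6.61 CPM (3.53 ± 0.31). Cell cycle genes had 2 of 35 called higher and 8 lower (2 and 8 adjusted over the list alone), and textbook miRNA targets 15 of 42 higher and 7 lower (16 and 7).

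By camera NF-kB targets (1.97e-27) held for dsRNA after VP55, with adjusted p = 0.0136 with an estimated correlation. Lost were interferon-stimulated genes (1.13e-19, then 0.119), interferons (5.67e-05, 0.117), cytokines (2.49e-13, 0.0823), histones (9.26e-13, 0.0502), matrix (1.96e-08, 0.0823), fibroblast identity (0.000539, 0.0823), cholesterol (1.77e-05, 0.117), p53 targets (2.05e-05, 0.0671), small non-coding RNA genes (0.000108, 0.164), miRNA host transcripts (0.00171, 0.267), textbook targets (0.00362, 0.145) and cell cycle (0.00793, 0.235). The host transcript call also ended without VP55+dsRNA replicate 1 (0.126). The edgeR test called 2481 genes higher and 1519 lower, 4000 in all, and 1459 and 1056 without overlapping genes, but 1869 higher and 2594 lower with library sizes in place of TMM scaling, which moved the median of all genes to −0.272. The total was 1842 without VP55 24 h replicate 2, 1539 without VP55+dsRNA replicate 1 and 928 with only these 2 groups in the fit.

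VP55 and GFP were also compared directly under dsRNA. Histones were higher with VP55, 15 of 55 (40 adjusted over the list alone), such as HIST1H4L at 24.1 ± 20.3 against 0.191 ± 0.27 CPM, a ratio of summed counts of 72.3 (95% interval 11.7 to 2980). The summed level of the 55 histone genes was 3160 ± 205 with VP55, 1440 ± 127 with GFP and 132 ± 14.8 CPM in mock cells. NF-kB targets were higher, 10 of 22 (16 adjusted over the list alone), such as RELB at 215 ± 14 against 64.5 ± 22.6 CPM (1.71 ± 0.27, mock 13 ± 4.49 CPM), and p53 targets, 4 of 24 (16 adjusted over the list alone), such as BTG2 at 939 ± 189 against 284 ± 113 CPM (1.74 ± 0.27). Of 54 interferon-stimulated genes 4 were called lower (22 adjusted over the list alone). UBE2L6, which attaches ISG15 to proteins, was at 58.6 ± 5.78 against 154 ± 25.2 CPM (−1.36 ± 0.25), and PLSCR1 at 126 ± 28.4 against 257 ± 21.2 CPM (−0.99 ± 0.22).

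**Figure D4:**
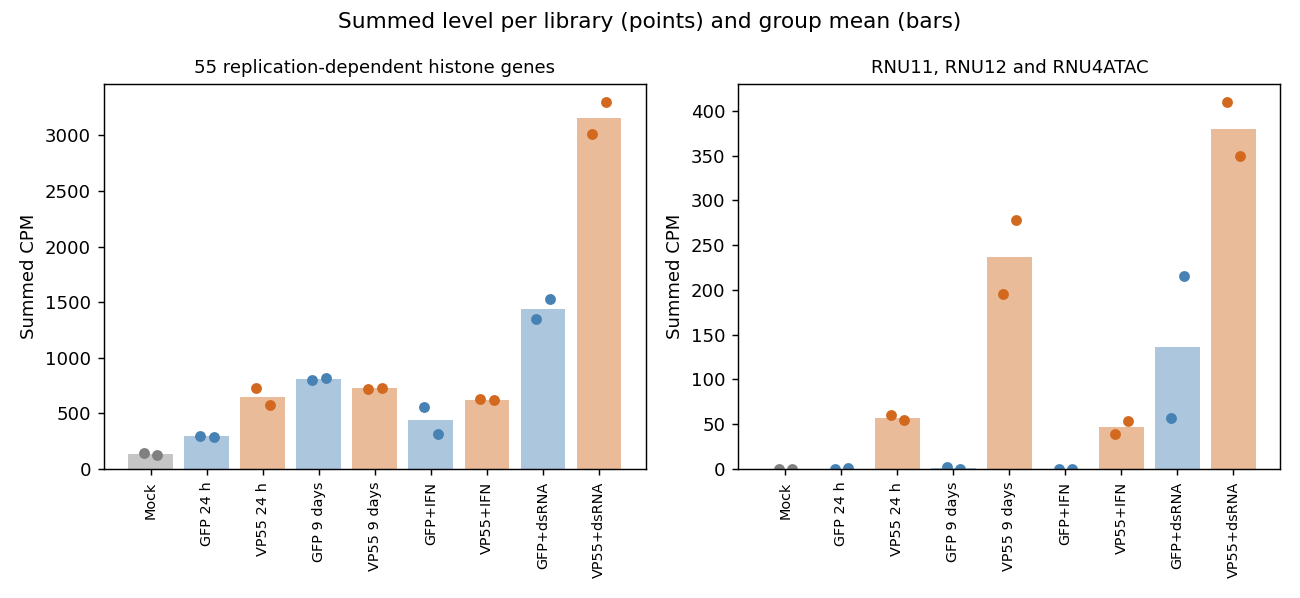
Summed level of 55 replication-dependent histone genes and of the minor spliceosome RNAs RNU11, RNU12 and RNU4ATAC per library in CPM, with points for libraries and bars for means of 2. Histones averaged 3160 CPM at VP55+dsRNA and 1440 CPM at GFP+dsRNA, but 724 CPM at VP55 9 day and 807 CPM at GFP 9 day.

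CDR1 was at 118 ± 137 against 0.762 ± 1.08 CPM under dsRNA (6.74 ± 1.3) and the lymphotoxin gene LTB at 25 ± 14.6 against 1.33 ± 0.272 CPM (3.95 ± 0.74). The edgeR test called 0 of 5 interferon genes, with 3 lower at an unadjusted p under 0.05 and 0 by DESeq2 (2 lower adjusted over the list alone). It called 0 of 35 cell cycle genes, with 14 higher at an unadjusted p under 0.05 and 0 by DESeq2. Textbook miRNA targets had 1 of 42 called higher (2 adjusted over the list alone) and small non-coding RNA genes 1 of 18 (3 adjusted over the list alone).

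Camera calls that held between VP55 and GFP under dsRNA were histones (1.69e-31, adjusted p = 0.00039 with an estimated correlation), p53 targets (8.83e-14, 0.00406) and NF-kB targets (3.27e-15, 0.0253). Interferon-stimulated genes (5.21e-22, lower) were lost at adjusted p = 0.135 with an estimated correlation, cell cycle (0.000172) at 0.135, interferons (0.00239, lower) at 0.252, small non-coding RNA genes (0.00118) at 0.261 and textbook targets (0.0224) at 0.261. The interferon call also ended without GFP+dsRNA replicate 2 (0.511) or VP55+dsRNA replicate 2 (0.152), the textbook call without GFP+dsRNA replicate 2 (0.199) or VP55+dsRNA replicate 1 (0.565), and the small RNA call without GFP+dsRNA replicate 1 (0.289). In all 179 genes were called higher and 45 lower, 224 in all, but 120 higher and 131 lower with library sizes in place of TMM scaling, which moved the median of all genes to −0.145. The edgeR test called 0 genes with only these 4 libraries in the fit (559 at an unadjusted p under 0.05) and DESeq2 139, while without 1 library the joint fit called 646 (GFP+dsRNA replicate 1), 786 (VP55+dsRNA replicate 1) or 1199 (VP55+dsRNA replicate 2).

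Whether VP55 changed the response to interferon was tested as an interaction, and 86 genes were called, all with a lower log2 fold change in VP55 cells. Of these 84 overlap another gene. MIF, for which GFP 24 h had 0 counts, was at least 193-fold higher with interferon after GFP and at −0.58 ± 0.28 after VP55, with −8.13 as the bound of the difference. TYMS, which makes thymidylate for DNA, differed by −2.5 ± 0.43, with an adjusted p of 0.91 without GFP+IFN replicate 2. Without overlapping genes 1 was called, COX20, chosen after its values were seen, which averaged 1.97 CPM in the 6 libraries and 45.4 CPM in the other 12. Of 54 interferon-stimulated genes the edgeR test called 0, with 1 lower at an unadjusted p under 0.05 and 0 by DESeq2, and camera missed the set at adjusted p = 0.725, though it was lower without VP55 24 h replicate 1 (0.0469). By camera miRNA precursors were lower (2 of 12 called, 2 adjusted over the list alone, adjusted p = 8.44e-08, and adjusted p = 0.0378 with an estimated correlation), a call lost with no low-count filter (0.462). Without overlapping genes cytokines (0.0433), histones (0.0433) and small non-coding RNA genes (0.000381) were lower as sets, which all missed over all genes (0.412, 0.434 and 0.404). Matrix genes were higher at 0.0171, lost at adjusted p = 0.955 with an estimated correlation. The call also ended without replicate 1 of GFP 24 h, GFP+IFN or VP55+IFN or replicate 2 of VP55 24 h. The 86 fell to 16 without GFP+IFN replicate 2, 29 without GFP 24 h replicate 2 and 56 without VP55 24 h replicate 2.

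For dsRNA the interaction called 36 genes, 35 with a lower log2 fold change in VP55 cells, of which 30 of the 36 overlap another gene. IL8 responded by 8.63 ± 0.73 after GFP and 4.28 ± 0.55 after VP55, a difference of −4.36 ± 0.86, and IL6 by 8.07 ± 0.59 and 3.96 ± 0.46, a difference of −4.12 ± 0.72. Their levels under dsRNA did not pass between VP55 and GFP (log2 fold change 0.96 for IL8, −0.09 for IL6), whereas before dsRNA both were higher with VP55. The adjusted p for IL8 was 0.0988 and 0.36 without GFP 24 h replicate 1 or 2 and 0.064 and 0.151 without VP55 24 h replicate 1 or 2, and for IL6 it was 0.0512 and 0.263 without GFP 24 h replicate 1 or 2. Of 37 cytokines 3 were called lower (6 adjusted over the list alone). By edgeR 0 genes were called without overlapping genes (540 at an unadjusted p under 0.05), with adjusted p = 0.117 for IL8 and 0.0692 for IL6, and DESeq2 over all genes called 27, with adjusted p = 0.071 for IL8.

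As sets in the dsRNA interaction, interferon-stimulated genes (6.82e-11), cytokines (9.43e-09), NF-kB targets (0.000577) and histones (0.000164) were lower and cell cycle (2.78e-07) and matrix genes (0.0143) higher by camera. All were lost with an estimated correlation, at adjusted p = 0.435, 0.265, 0.406, 0.265, 0.185 and 0.53. Without overlapping genes small non-coding RNA genes (0.0344) and the stress response list (0.0424) were lower, which missed over all genes (0.379 and 0.313). The matrix call ended without GFP 24 h replicate 1 (0.0813), VP55 24 h replicate 2 (0.117), GFP+dsRNA replicate 1 (0.0568) or VP55+dsRNA replicate 2 (0.364), and the histone call without GFP 24 h replicate 2 (0.0889) or VP55+dsRNA replicate 1 (0.0528). The NF-kB call ended without GFP+dsRNA replicate 2 (0.0716) and that of interferon-stimulated genes without VP55+dsRNA replicate 2 (0.0553). The 36 calls became 12 without GFP 24 h replicate 2, 21 and 19 without VP55 24 h replicate 1 or 2, 60 without GFP+dsRNA replicate 1, 286 without VP55+dsRNA replicate 1 and 220 without VP55+dsRNA replicate 2, and 9 with only the groups compared.

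The effect of VP55 at 9 days differed from that at 24 h for 718 genes, 325 with a larger and 393 with a smaller log2 fold change. Among those larger at 9 days, IL11 had an effect of 0.84 ± 0.45 at 24 h and 4.99 ± 0.35 at 9 days (difference 4.15 ± 0.55), and PTGS2 1.23 ± 0.39 and 4.11 ± 0.41 (2.88 ± 0.54). The chemokine CXCL12 had −0.38 ± 0.24 and −3.39 ± 0.3 (−3.01 ± 0.39), and COL5A3 −0.14 ± 0.3 and 2.22 ± 0.27 (2.36 ± 0.4). Of 22 NF-kB targets 4 were called larger (4 adjusted over the list alone), of 18 cholesterol genes 2 (4), and of 55 histones 5 smaller (6), each in brackets as adjusted over the list alone. By camera cell cycle (0.000437), cholesterol (0.000437) and NF-kB targets (0.00837) were larger and histones (0.00136), miRNA precursors (0.00136) and interferon-stimulated genes (0.0347) smaller. All were lost with an estimated correlation, at adjusted p = 0.395, 0.451, 0.474, 0.395, 0.395 and 0.927. The last also ended without GFP 24 h replicate 2 (0.124), VP55 24 h replicate 2 (0.503), GFP 9 day replicate 1 (0.0568) or VP55 9 day replicate 1 (0.119). Without overlapping genes 185 were larger and 113 smaller, and with library sizes in place of TMM scaling 188 and 675, with the median of all genes at −0.31. The 718 fell to 396 and 314 without GFP 24 h replicate 1 or 2, 210 without VP55 24 h replicate 2, 324 and 371 without GFP 9 day replicate 1 or 2, and 281 and 446 without VP55 9 day replicate 1 or 2.

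The 4 direct comparisons of VP55 with GFP share no library. EGR1, PPP1R10, a phosphatase subunit, and ZBTB20, a repressor that overlaps another gene, were called higher in all 4, and were chosen after their values were seen. EGR1 differed by 3.07 at 24 h, 5.31 at 9 days, 4.87 under interferon and 1.31 under dsRNA, where its call was lost without GFP+dsRNA replicate 1 (adjusted p = 0.0843). PPP1R10 differed by 1.58, 2.56, 1.46 and 1.11, and under interferon its call was lost with any of the 4 libraries left out (0.109 to 0.709). ZBTB20 differed by 4.20 at 24 h, by 4 at 9 days and by 1.87 under dsRNA and was at least 23.6-fold higher under interferon, but calls were lost without GFP 24 h replicate 2 (0.321), VP55 24 h replicate 2 (0.17) and, under interferon, GFP+IFN replicate 2 or VP55+IFN replicate 2 (0.855 and 0.211), and under dsRNA without GFP+dsRNA replicate 1 or 2 (0.0947 and 0.0719) or VP55+dsRNA replicate 2 (0.217). At 24 h, under dsRNA and at 9 days 26 genes were called higher, BTG2, MDM2, NFKB1 and NFKB2 among them.

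Genes called higher in 2 of these comparisons numbered 86 for 24 h and 9 days, where independent draws would give 36.6, with 2 shared lower and 23 in opposite directions. They numbered 104 for dsRNA and 9 days against 25.3, 34 for 24 h and dsRNA against 3.76, and 12, 9 and 4 for interferon with 9 days, 24 h and dsRNA, against 1.84, 0.273 and 0.189. Without overlapping genes the 6 counts were 33, 58, 17, 7, 4 and 3. Across genes the effects had a Pearson correlation of 0.18 to 0.28, and genes are not independent replicates.

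Genes with a seed site for an miRNA in the 3′ UTR, which would rise if that miRNA were lost, were compared with matched sets in the 4 VP55 comparisons. At 24 h the sets of 8 of 27 fibroblast families lay higher, led by miR-26 (0.079 above its matched sets, with an SD of 0.0178 between random sets), and those of miR-125 (−0.090) and miR-214 (−0.038) lay lower. None of the 7 control families passed, with 1 lower at an unadjusted p under 0.05, but with 7mer-m8 sites added 2 of these 7 and 5 of the 27 lay lower. The let-7 set differed by −0.017, with an SD of 0.0184. At 9 days, under interferon and under dsRNA 0 of 27 passed by random sets, with smallest adjusted p of 0.706, 0.286 and 0.939 and 1, 2 and 0 families at an unadjusted p under 0.05. Camera called 0 families in any of the 4 comparisons.

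With length and expression matched in 5 bins each, 9 families lay higher at 24 h and 2 under interferon. With GC content of the 3′ UTR matched as well in these bins, 1 family passed at 24 h, miR-26 at 0.055 (adjusted p = 0.0238). By that last test miR-181 lay 0.089 higher at 9 days (0.0476) and miR-30 lay 0.053 higher under interferon (0.0136). The 8 families became 0 without GFP 24 h replicate 1 or without VP55 24 h replicate 2, and 4 rather than 0 passed under interferon without VP55+IFN replicate 1.

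**Figure D5:**
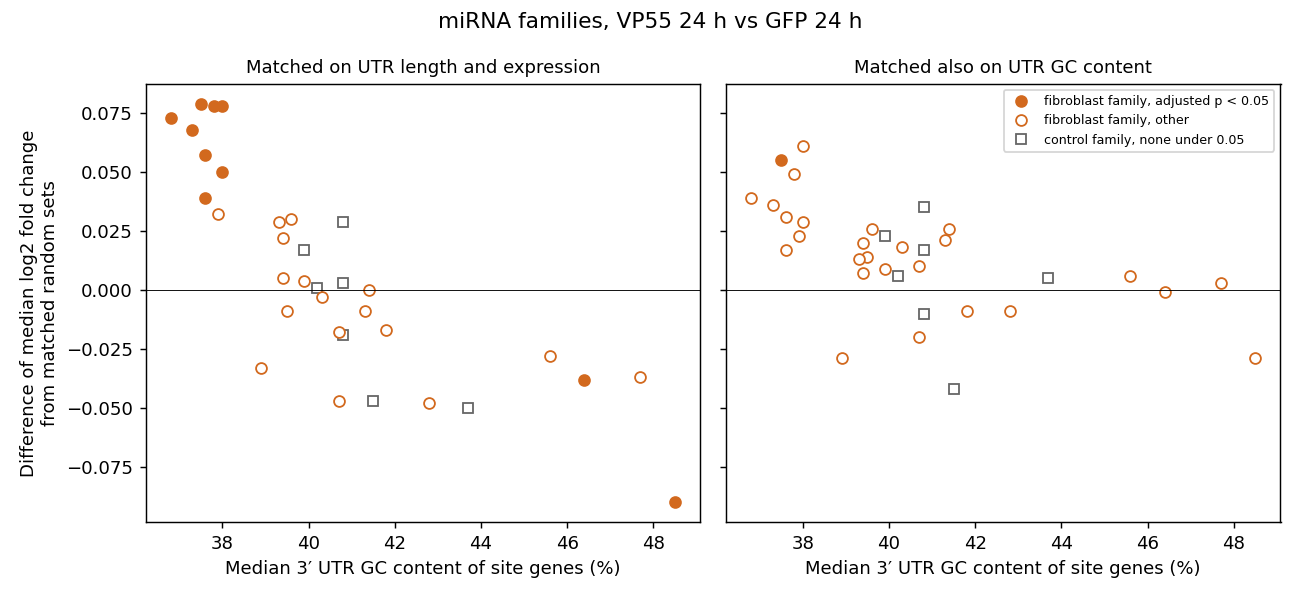
Difference between genes with a seed site and their matched random sets in log2 fold change, VP55 against GFP at 24 h, against the median GC content of the 3′ UTRs with the site in percent; each point is an miRNA family. Families that lay higher had 36.8% to 38.0% GC and those that lay lower 46.4% to 48.5%, and with sets matched on GC and on length and expression in 5 bins 1 of 27 passed the threshold.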

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

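All results in this part are effects that differed between groups, as tested by an interaction in edgeR. The tests of explanations below were chosen after the result was seen.

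The response to interferon differed between VP55 and GFP cells for 86 genes, of which 84 overlap another gene. Among these 84 were MIR1282 (−11.5), MIF (−11.28) and TYMS (−2.5). The response to dsRNA differed for 36 genes. Among these it was smaller in VP55 cells for the cytokines IL8 (−4.36), IL6 (−4.12) and CCL2 (−2.07), the NF-kB inhibitor TNFAIP3 (−2.1) and HIST1H4E (−2.88), and larger for LBH (1.93). Without overlapping genes the calls of IL8, IL6, CCL2, HIST1H4E and LBH were lost (adjusted p = 0.0692 to 0.205), and with only the groups compared those of CCL2, HIST1H4E, LBH, TNFAIP3 and SCO2 (0.086 to 0.434). SCO2, which overlaps another gene, had a fitted difference of −13.93, higher with dsRNA after GFP and lower after VP55. Fitted values of genes with 0 counts in a group are not sizes, and at 3 counts over such a group the differences were −7.97 for MIR1282, −8.13 for MIF and −5.5 for SCO2. The gap between VP55 and GFP cells at 24 h entered each of these cytokine differences. For IL8 VP55 24 h did not pass against mock (0.41, adjusted p = 0.648).

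The effect of VP55 differed between 9 days and 24 h for 718 genes. It was larger at 9 days for the matrix proteases MMP10 (5.76) and MMP3 (5.38), the cytokines IL11 (4.15) and LIF (3.72), and the NF-kB targets PTGS2 (2.88), IER3 (2.27), TNFAIP3 (1.84) and NFKB1 (1.61). It was also larger for the cholesterol gene INSIG1 (2.72), the cell cycle genes UBE2C (3.15) and TOP2A (2.28), the collagens COL5A3 (2.36) and COL6A1 (1.83), and FOSB (fitted 12.28, at least 8.34 by its 0 counts at VP55 24 h). It was smaller or more negative for CXCL12 (−3.01), POSTN (−2.38), TAP1 (−2.11), PLSCR1 (−1.32), ASNS (−2.81), MIR143HG (−4.47), HIST1H1D (fitted −6.75) and MIF (fitted −10.4), of which 0 counts at GFP 24 h leave −3.45 and −6.96 as bounds. With the 9 day pairs summed the calls of MMP10, LIF, IER3, TNFAIP3, NFKB1, UBE2C, TOP2A, COL6A1, POSTN, PLSCR1 and HIST1H1D were lost (adjusted p = 0.081 to 0.183), and without overlapping genes those of MMP10, IER3, UBE2C, PLSCR1 and HIST1H1D (0.0514 to 0.0598).

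Many of these differences came from overlapping genes near 0 in 6 libraries, a pattern with technical explanations and a biological one. Reads over 2 genes may have been counted differently in those libraries: the shift of overlapping genes at VP55 24 h was 0.313, and the 8 mixed results had shifts of 0.313 to 0.682 in size. The test stayed open because VP55+IFN against GFP+IFN, which mixes no such libraries, had −0.134 where at most 0.1 in size was asked for, and VP55 9 day against GFP 9 day had −0.237. Strand-specific counting was excluded, since MIF fell to 0% and LOC284889, its neighbour on the opposite strand, to 5.67% of the other 12 libraries. VP55 as the cause was excluded, since the overlapping genes higher with VP55 at 24 h stood at 23.6% in VP55+dsRNA libraries of their level in mock, GFP 9 day and GFP+IFN libraries.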

How the results depend on the processing

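Of 397 gene results of the text, DESeq2 lost 47, RLE scaling 6, library sizes 9, no low-count filter 2, a strict filter 3 and the replicate block 3. With each library left out in turn 236 were never lost, and of the 98 list calls 20 were lost at least once. Of 275 gene results recomputed without overlapping genes, 21 were lost. The alternatives listed above as added were chosen after seeing the data. Where no cause is given, the cause was not tested.

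Left out in turn, single libraries moved the call counts as follows, and the cause was not tested. GFP 24 h against mock ranged from 725 to 1279, VP55 24 h from 63 to 177, VP55 9 day from 1222 to 2195 and GFP 9 day from 1809 to 2467. GFP+IFN ranged from 66 to 729, VP55+IFN against VP55 from 97 to 230 and against GFP+IFN from 1 to 8. GFP+dsRNA ranged from 2766 to 4536, VP55+dsRNA against VP55 from 1539 to 4972 and against GFP+dsRNA from 175 to 1199. The interactions ranged from 16 to 83 for interferon, 12 to 286 for dsRNA and 210 to 495 for time. Seed families higher at 24 h ranged from 0 to 9 and under interferon from 0 to 4, and were 0 throughout at 9 days and under dsRNA.

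Without overlapping genes, where fewer genes were tested, the calls were 1111 for GFP 24 h against mock, 42 for VP55 24 h, 2198 for VP55 9 day, 2257 for GFP 9 day, 346 for GFP+IFN, 8 for VP55+IFN against GFP+IFN, 3176 for GFP+dsRNA, 2515 for VP55+dsRNA and 118 for VP55+dsRNA against GFP+dsRNA. The interactions had 1 for interferon, 0 for dsRNA by edgeR (540 at an unadjusted p under 0.05) and 298 for time. Calls shared with VP55 24 h were 4 under interferon, 17 under dsRNA and 33 at 9 days, and those shared with 9 days were 7 under interferon and 66 under dsRNA (58 higher and 8 lower).

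With only the groups compared in the fit the calls were 4112 for GFP 24 h against mock, 537 for VP55 24 h, 6523 for VP55 9 day, 6078 for GFP 9 day, 549 for VP55+IFN against VP55 and 169 against GFP+IFN. They were 928 for VP55+dsRNA against VP55 and 0 by edgeR for VP55+dsRNA against GFP+dsRNA (559 at an unadjusted p under 0.05). The interferon, dsRNA and time interactions had 153, 9 and 2657.

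DESeq2 called 1131 for GFP 24 h against mock, 1857 for VP55 9 day, 2267 for GFP 9 day, 461 for GFP+IFN, 43 for VP55+IFN against GFP+IFN, 2998 for GFP+dsRNA, 2535 for VP55+dsRNA against VP55, 139 for VP55+dsRNA against GFP+dsRNA and 396 for the time interaction. Without a low-count filter the calls were 75 for VP55+IFN against GFP+IFN, 630 for VP55+dsRNA against GFP+dsRNA, and 139 and 138 for the interferon and dsRNA interactions. A strict filter gave 20 for VP55+IFN against GFP+IFN, and library sizes gave 62 for the dsRNA interaction. The small non-coding RNA list reversed without a filter, at adjusted p = 0.52 for VP55 24 h and 0.399 for VP55 9 day.

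Library sizes in place of TMM moved the median of all genes for GFP 24 h against mock to −0.135, GFP+IFN to −0.189, VP55+IFN against VP55 to −0.172, GFP+dsRNA to −0.016 and the dsRNA interaction to −0.209. With an estimated correlation 19 of 98 list calls were kept. With the 9 day pairs summed the calls were 1096 for VP55 9 day, 2122 for GFP 9 day and 243 for the time interaction, and the cause was not tested.

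Replicate numbers do not pair libraries: deviations correlated between −0.125 and 0.26 over 36 pairs of groups. With a replicate block the calls stayed within 1.5 times, such as 267 for VP55 24 h and 19 for VP55+IFN against GFP+IFN. A crossed block gave 348 for VP55+dsRNA against GFP+dsRNA. Seed families higher with sets matched on GC content numbered 1 at 24 h, 1 at 9 days and 1 under interferon, those with sets in 5 bins of length and expression 9 at 24 h and 2 under interferon, and 7mer-m8 sites added to 8mer sites gave 1 under interferon. The cause was not tested.

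With mock in place of GFP 24 h the calls were 1651 for VP55 24 h and 2045 for GFP+IFN, and signs reversed. For VP55 24 h interferon-stimulated genes were higher (1.02e-18), matrix genes missed on the higher side (0.328), CXCL1 was at −0.39, LBH 0.33, MIR1282 −0.26, MIF −0.2, TYMS −1 and EGR1 −0.48. For GFP 9 day interferon-stimulated genes missed on the higher side (0.241), with DCN at −0.05, PDGFRA −0.22, IFI27 3.68, IFIT1 0.02, MX1 0.33, BST2 1.72, TP53I3 0.41, CD68 0.2, MIF −0.36 and MIR1282 −0.06. For GFP+IFN p53 targets (0.0473) and matrix genes (0.0048) were higher and cholesterol genes missed on the higher side (0.259), with MIF at −0.19 and MIR1282 at −0.27. The reference itself changed, as GFP 24 h differed from mock by 2147 calls.

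Other reversals came with 1 library left out, and the cause was not tested. In VP55+IFN against GFP+IFN small non-coding RNA genes were higher without GFP+IFN replicate 1 (0.00285) and lower without replicate 2 (2.51e-07), with 0.783 as the largest adjusted p. Interferon-stimulated genes were lower without GFP+IFN replicate 1 (0.000814) and histones higher (1.74e-20), while without replicate 2 both missed, on the higher (0.27) and the lower side (0.252). In VP55+dsRNA against GFP+dsRNA cytokines were lower without GFP+dsRNA replicate 1 (0.00185) and higher without replicate 2 (0.00429), with 0.376 as the largest adjusted p. There the miRNA host transcripts were lower without VP55+dsRNA replicate 1 (1e-04) and higher without replicate 2 (0.000851), with 0.568 as the largest. In the dsRNA interaction they were lower without VP55+dsRNA replicate 1 (0.0184) and higher without replicate 2 (0.000541), with 0.993 as the largest.

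Among genes, KRT8 and DSP in GFP+IFN against GFP 24 h were at −0.03 and −0.02 without GFP+IFN replicate 2 and at 1.84 and 1.4 without replicate 1. HMMR and PECAM1 in VP55+dsRNA against VP55 were at −1.78 and 0 without VP55+dsRNA replicate 1 and at 2.67 and 8.95 without replicate 2. The cause was not tested. In the shallowest library 1 count equals 17.6 CPM, which limits what GFP+IFN can show of weak genes.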

Other observations

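Tests of miRNA loss, of 3′ UTR length or base composition and of S phase by the median of the cell cycle list were written before the result was seen. Other tests, and the reasons that left these open, came after it.

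Markers of other cell types were few. KRT18, found in simple epithelia and overlapping another gene, was at 105 CPM in mock cells, 238 CPM at GFP 24 h and 34.1 CPM at GFP 9 day. DSP, a desmosome gene, was at 54 CPM in mock cells, 100 CPM at GFP 24 h and 330 CPM at GFP+dsRNA. The macrophage marker CD68 was at 86 CPM in mock cells and 183 CPM at GFP 24 h. The polynucleotide phosphorylase gene PNPT1 was at 26.3 ± 1.53 CPM at GFP 24 h and 275 ± 66.2 CPM at GFP+dsRNA (3.37 ± 0.44), and MIR143HG, an overlapping host transcript, at 2.01 ± 0.189 against 89.6 ± 5.15 CPM for VP55 against GFP at 9 days.

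The first hypothesis was that loss of fibroblast miRNAs raised genes with their seed sites, which might show as many families shifted upwards. By the test written beforehand, with sets matched on length and expression, 8 of 27 such families and 0 of 7 control families were shifted upwards at 24 h, the highest number of any VP55 comparison. Of the 4 direct comparisons only this one mixes the 6 libraries with others, so counting of overlapping genes stayed open too. In 5 bins of length and expression GC matching moved the number at 24 h from 9 to 1 but the median difference of the 27 families from 0.006 to 0.017 and those above 0 from 17 to 21, so loss of repression by the miRNAs abundant in fibroblasts stayed open. For 3′ UTR length or base composition the share of families shifted upwards was 29.6 percentage points above that of control families at 24 h, which left it open too, because the control families' site genes had 39.9% to 43.7% GC while the families that lay higher had 36.8% to 38.0%. GC content of the 3′ UTR fitted: 7 of the 8 families no longer passed with GC matched, and the 8 differences moved from 0.039 to 0.079 down to 0.017 to 0.061, all still above 0, so base composition may account for part of those shifts.

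The histone list was higher with VP55 by camera in all 4 comparisons, lost with an estimated correlation at 9 days (adjusted p = 0.352) and under interferon (0.164), and the small non-coding RNA list in 3 of 4, all lost (0.403, 0.357 and 0.261). The first biological explanation was more cells in S phase. At 24 h the histone call held (adjusted p = 0.00851 with an estimated correlation). The cell cycle list there had a median of −0.17 and an upper quartile of 0.088, below the histones' lower quartile of 1.228. These values argue against more cells in S phase as the cause of the histone rise at 24 h. They do not exclude it, because the list pools genes of DNA replication and of mitosis, and S-phase genes were not tested alone. Histones were higher with a cell cycle median at or below 0 in 2 comparisons, 24 h and interferon (−0.09), and without overlapping genes the cell cycle list was lower in both (0.00248 and 0.0423, but adjusted p = 0.193 and 0.408 with an estimated correlation), yet more cells in S phase stayed open under interferon, where the histone call was lost. At 9 days and under dsRNA the explanation stayed open: the cell cycle list was higher in 2 of 2 comparisons, with medians of 1.18 and 0.69, but with adjusted p = 0.357 and 0.135 with an estimated correlation.

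VP55, a poly(A) polymerase, could add tails to RNAs that lack them and so bring them into libraries selected for poly(A). For histones their summed level was higher in both VP55 libraries in 3 of 4 conditions, but 724 against 807 CPM at 9 days. It also rose without VP55, at 132 CPM in mock cells, 296 at GFP 24 h, 807 at GFP 9 day and 1440 at GFP+dsRNA. Tailing stayed open, because abundant genes such as HIST1H2BK (128 against 269 CPM at 9 days) weigh on that sum. At 9 days the list was higher by camera (adjusted p = 0.00866, but 0.352 with an estimated correlation). For small RNA genes tailing also stayed open. The list was higher in 3 of 4 comparisons, of which 24 h and 9 days turned lower with no low-count filter (0.52 and 0.399). RNU11, RNU12 and RNU4ATAC, chosen after seeing the data, summed higher in both VP55 libraries in all 4 conditions. At GFP+dsRNA the sum was 137 ± 112 CPM, against 57.2 ± 3.89 CPM at VP55 24 h. Carry-over of untailed RNA into some libraries also stayed open: in GFP+IFN replicate 1, where RMRP and RPPH1 summed to 2280 CPM, histones summed to 562 CPM from 32 counts, with a 95% interval of 385 to 794 CPM that includes the 626 and 620 CPM of the VP55+IFN libraries.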
